A study of Mus musculus with 2 samples.

How the data were processed

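RNA was measured in luminal epithelial cells of the mouse mammary gland, isolated by fluorescence-activated sorting. The control library (Ctrl) came from mice carrying the floxed cluster of miR-200c and miR-141 without a Cre driver. The knockout library (CKO) came from mice that also carried K8-CreERT2, a tamoxifen-inducible Cre recombinase driven by the keratin 8 promoter. Since only CKO carried the Cre driver, its effects cannot be told apart from those of the deletion. Per the labels the mice were C57BL/6 and 8 weeks old, about 20000 cells were sorted, and a low-input library was sequenced on an Illumina HiSeq. The labels give the interval after tamoxifen as 4 weeks in one field and as 3 days in another, so the interval is not known. There was 1 library per group and no replicate, and the number of mice behind each library is not stated.

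The authors' processing notes name HISAT, Bowtie2, RSEM and the mm10 genome, without versions. The deposited table holds 16906 genes with 1 expression value per gene and library. The header of these columns gives no unit. The deposited values are FPKM (fragments per kilobase of transcript, scaled to library size): multiplied by the length column in kilobases they summed to 999609 in Ctrl and 999909 in CKO. They are rounded to 2 decimals, and a gene without reads is listed at a floor of 0.01. The deposited log2 fold change equalled the log2 ratio of the FPKM columns, CKO over Ctrl. The deposited p-value and its false discovery rate come from the authors' test of the reads of 1 library against the other, so they compare the libraries and not the conditions. The authors' calls of up and down matched a false discovery rate of at most 0.001 with at least a 2-fold difference. Symbols stored as dates were restored from the gene identifier for 23 genes. The identifiers of 16796 genes matched the reference gene table and 110 did not.

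The plan, made before the data were examined, assumed read counts scaled by the trimmed mean of M-values. The table holds no counts, so the fallback named in that plan was used: the deposited FPKM with 0.5 FPKM added and no further scaling. All log2 ratios are CKO over Ctrl on that scale unless stated. Genes with at least 5 FPKM in the higher library and at least a 2-fold ratio were counted as higher or lower. No test across samples was possible with 1 library per group, and no p-value was computed. The ratios have no replicate check.

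The number of reads behind each value was estimated from the deposited p-values. Genes listed at the floor in 1 library gave p-values that were powers of a single share, and 133 of 133 such genes returned a whole number of reads within 0.01. The share of CKO in the reads of both libraries was 0.4779. A fit to the p-values of 11189 genes gave about 12500000 reads in Ctrl and 11400000 in CKO, with a median absolute difference of 0.0636 on the log10 scale. Estimated reads were FPKM times kilobases times these totals. Each ratio carries a 95% exact conditional binomial (Clopper-Pearson) interval of the read ratio, computed without the added 0.5 FPKM, so for weakly expressed genes the printed log2 ratio can lie outside it. These intervals and the floor of 3 reads cover counting error only, since reads copied by PCR are not independent molecules. A fold against a library with no reads was computed against 3 reads, as a convention and not a bound.

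Gene lists, 28 in all, were fixed before the data were examined. A list member counted as measured with a mean of at least 1 FPKM, and as higher or lower with a ratio of at least 1.5-fold and an interval that excluded a ratio of 1. Each list was described by its median log2 ratio and the percentile of that median among 10000 random lists of equal size. Random lists were matched on mean expression in 20 bins, and also on expression and transcript length in a grid of 10 by 10 bins. The percentile is a description and not a test.

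Seed matches were sought in the longest annotated 3' UTR of each gene (GENCODE M21 on GRCm38), as the 7-mer CAGTATT for miR-200c-3p and CAGTGTT for miR-141-3p. UTRs under 30 bases were left out. Genes with a match to either were compared with genes with neither by the difference of medians. The median of the genes with a match was placed among the medians of 10000 random gene lists matched on expression and UTR length. Each 7-mer was also ranked among the permutations of its bases found in at least 100 genes, counting those with as high a difference after adjustment for UTR length and expression.

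The named genes followed a rule fixed in advance. It took the 15 genes with the highest and the 15 with the lowest ratios by the interval bound nearest to 0, among genes of at least 5 FPKM. It added Ccnd1, Esr1, Pgr, Greb1, Areg, Zeb1, Zeb2 and Krt8, up to 4 members of each list by the same bound, and the 5 most abundant genes. Other genes named were chosen after their values were seen and are introduced as such. Mir200c, Mir141 and Xist are not analysed here, nor are the mitochondrially encoded genes, since the table has no line for them.

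Alternatives covered the added value, the filter on low values, the scaling, the values used, the treatment of gene length, the genes counted and the matching of the random lists. The analysis was tested on simulated libraries. It recovered 50 of 50 genes planted at 4-fold and 50 of 50 at 0.25-fold. It recovered 16 of 50 at exactly 2-fold and 18 of 50 at 0.5-fold, which lie on the threshold. Of 8518 unchanged genes 0 passed, and 95.3% of the intervals held the simulated ratio. These libraries were simulated with counting noise only, without spread between animals or copied reads, so the outcome covers counting error alone. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.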

Results

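Expression was measured by bulk RNA sequencing in sorted luminal mammary cells of mice with the cluster of miR-200c and miR-141 intact (Ctrl, 1 library) and after its inducible deletion (CKO, 1 library). MicroRNAs are short RNAs that lower the output of messenger RNAs matching their seed, and this cluster is best known for repressing Zeb1 and Zeb2 in epithelial cells. About 12500000 reads lay behind the Ctrl values and 11400000 behind the CKO values, both estimated from the deposited p-values. Above the floor of the table were 16204 genes in Ctrl and 16000 in CKO. The 5 genes with the highest FPKM held 3.22% of the reads in Ctrl and 4.05% in CKO. The luminal keratin gene Krt18 was the highest, at 6606.79 FPKM in Ctrl and 10398.36 in CKO, and its partner Krt8 stood at 3871.08 and 4476.23. The others were the translation factor Eef1a1 at 4765.07 and 4971.21 FPKM, the actin gene Actg1 at 3266.48 and 3855.71, and the ribosomal gene Rplp1 at 2562.59 and 3231.97. There are no replicates, so no difference given here has been checked against the spread between animals.

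The comparison of CKO with Ctrl asked what changes in luminal cells when the cluster is removed, with Ccnd1 and the estrogen receptor named in the study's title. Ccnd1, which encodes the G1 cyclin D1, was 1.65-fold higher in the CKO library, at 11.95 FPKM in Ctrl and 19.74 in CKO. Esr1, the gene of estrogen receptor alpha, was at 24.48 and 28.28 FPKM. Of 18 measured markers of basal myoepithelial cells, 10 were at least 1.5-fold higher in the CKO library and 1 lower. Of 11 measured genes of G2 and mitosis 6 were higher and 0 lower, but 4 of these 6 were under 1 FPKM in Ctrl. Of 18 milk protein and lactation genes, 5 were lower and 3 higher. The lowest ratios included Ifi202b, an interferon-inducible gene, at 35.03 FPKM in Ctrl and 0.44 in CKO.

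Among 8870 genes with at least 5 FPKM in the higher library, 58 were at least 2-fold higher in CKO and 31 at least 2-fold lower, while 96.4% lay within 1.5-fold. The authors' table calls 104 genes up and 108 down with no such minimum, and all 58 and all 31 genes are among those calls. The log2 FPKM of the libraries correlated across these genes with a Pearson r of 0.974, where genes are not independent replicates. The counts depended on how values were formed. Without division by length, a choice made after the data were seen, 68 genes were higher and 69 lower, and with a minimum of 1 FPKM in place of 5 they were 110 and 91.

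**Figure D1:**
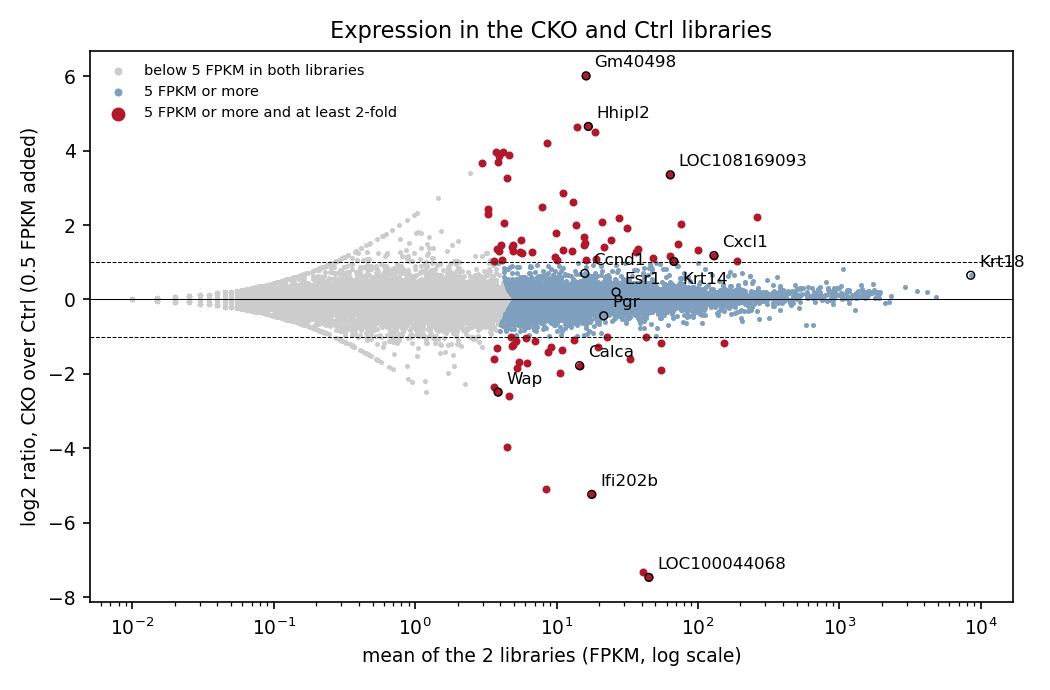
Each point is a gene, with the mean of the Ctrl and CKO libraries (FPKM, log scale) on the horizontal axis and the log2 ratio of CKO over Ctrl on the vertical axis. Dashed lines mark a 2-fold difference, red points are the 58 higher and 31 lower genes, and circled genes are named in the text.

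The genes with the largest ratios toward CKO were led by predicted loci and histocompatibility genes. Gm40498 had 0 estimated reads in Ctrl and 32.35 FPKM in CKO, 384-fold higher against the conventional 3 reads. The pseudogenes Tdg-ps and Gapdh-ps15 also had 0 reads in Ctrl and were 73.2-fold and 38.2-fold higher on the same convention. Hhipl2, related to hedgehog-interacting protein, was at 0.82 FPKM in Ctrl and 32.75 in CKO. The class I histocompatibility family on chromosome 17 encodes antigen-presenting proteins, although some members are pseudogenes. Its member H2-Q10 had 1 read in Ctrl and 140 in CKO, a ratio of 138 with a log2 interval of 4.76 to 12.57. H2-Bl was at 0.43 and 16.59 FPKM, H2-T10 at 2.05 and 13.82, and Gm10499, described as a gene of the same class, at 0.61 and 27.18. GENCODE annotates H2-Bl, H2-T10 and Gm10499 as kinds of pseudogene. Upk3a, a uroplakin of the urothelial surface, was at 2.29 and 19.8 FPKM. LOC108169093, described as an envelope protein, a kind of protein that retroviruses carry, was at 10.97 and 116.6 FPKM. The other named loci were Gm41885, Gm40525, LOC547349 and LOC108167918, whose FPKM in Ctrl lay between 0.07 and 1.15 and in CKO between 7.71 and 36.57. LOC547349 had 1 read in Ctrl and 108 in CKO, a ratio of 110.1 whose log2 interval ran from 4.37 to 12.20.

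The genes with the largest ratios toward Ctrl were led by the Ifi200 family, interferon-inducible sensors of DNA clustered on chromosome 1. LOC100044068, described in the table as Ifi202b, was at 89.99 FPKM in Ctrl with 0 reads in CKO, 670.4-fold lower against the conventional 3 reads. Ifi202b itself was at 35.03 and 0.44 FPKM, Ifi203 at 8.27 and 0.95, Mndal at 5.63 and 1.54, and LOC102641031 at 8.86 and 0.1. Gm7429, a locus resembling a ribosomal protein gene, had 0 reads in CKO. On the same convention Gm7429 was 134-fold lower and Gm5601 94.6-fold lower. The calcitonin genes Calca and Calcb, peptide hormone genes, were 3.63-fold and 4.33-fold lower in CKO. The milk whey protein gene Wap was at 6.9 and 0.82 FPKM, the potassium channel gene Kcnh6 at 86.81 and 22.71, and the peptide transporter gene Slc15a2 at 50.08 and 16.35. Cdk5rap1, which encodes an RNA-modifying enzyme, was 3.69-fold lower, the annexin gene Anxa8 3.70-fold lower, and the histone gene Hist1h4k was at 6.35 and 0.83 FPKM with 32 and 4 reads. The deposited p-value of Slc15a2 implies a larger read difference, of -4.53 on the log2 scale, than its FPKM ratio of -1.59.

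Ccnd1 (Entrez gene 12443) lies on chromosome 7 at 144929931 to 144939925 of GRCm38. Its log2 ratio was 0.70, with a counting interval of 0.57 to 0.88, from about 568 reads in Ctrl and 859 in CKO. The deposited false discovery rate for Ccnd1 was 2.28e-19 in the authors' test between the libraries, and the gene did not reach the 2-fold rule. The 3' UTR of Ccnd1, 2676 bases long, holds 1 match to the miR-141-3p seed, CAGTGTT, at 144931651 to 144931657 on the minus strand, in exon 5 of 5. It holds no 7-mer for miR-200c-3p.

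Esr1 (Entrez gene 13982) lies on chromosome 10 at 4611593 to 5005614. Its log2 ratio was 0.20 from FPKM, with an interval of 0.09 to 0.32. The deposited p-value for Esr1 was 0.628 in the authors' test between the libraries. A p-value gives no direction, and on the side of the FPKM ratio it implies a log2 read ratio of 0.03. The FPKM and the deposited test thus differ for this gene. Of 11624 genes compared, 829 (7.13%) differed by more than 0.1 on the log2 scale. For some list members this crosses 1.5-fold. The implied log2 read ratios were -0.44 for Flt1, 0.45 for Bcl2 and -0.39 for Ccng1, all counted below as past it. For Mylk, a basal marker chosen after its values were seen and not counted, it was 0.83. The 3' UTR of Esr1, 4191 bases long, holds no seed match. Pgr (Entrez gene 18667), the progesterone receptor gene and a classic estrogen target, was at 24.9 and 18.24 FPKM, a log2 ratio of -0.44 with an interval of -0.55 to -0.35. Areg, which encodes the amphiregulin that relays estrogen signals in the gland, was at 263.35 and 302.47 FPKM. Greb1, another estrogen target, was at 0.42 and 0.34 FPKM, where the interval of -1.01 to 0.40 holds no difference.

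Known targets of the cluster went both ways. Of 24 measured genes from a literature list of miR-200c and miR-141 targets, 1 was higher (Ccnd1) and 1 lower (Flt1, a VEGF receptor gene, at 2.32 and 1.37 FPKM). The median log2 ratio was 0.03, at percentile 86.9 of random lists matched on expression and 99.5 with length matched too. Notch1, a signalling receptor gene, had a log2 ratio of -0.39, and Crtap, a collagen-modifying gene, 0.46. Zeb1 and Zeb2, repressors of epithelial genes with 9 seed matches each, were scarcely expressed: Zeb1 stood at 0.31 FPKM in both libraries, and Zeb2 at 0.24 and 0.4. Neither difference was detectable at this depth.

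Genes carrying seed matches in their 3' UTR lay no higher in the CKO library than matched genes. The 2610 genes with a match had a median log2 ratio of -0.07 and the 6147 genes without one a median of 0.01, a difference of -0.07. Random lists matched on expression and UTR length, drawn from all tested genes, had medians from -0.07 to -0.06. The median of the genes with a match lay at percentile 14.9 of them. Of the genes with a match, 6 were at least 2-fold higher and 5 at least 2-fold lower. Of 403 permutations of the miR-200c-3p 7-mer, 43 gave as high a difference, and for miR-141-3p it was 206 of 402.

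Estrogen receptor targets showed no common direction. Of 21 measured targets, 1 was higher (Ccnd1) and 1 lower (Calca), and the median was -0.01, at percentile 33.3 of the expression-matched lists. Myc, the proliferation-linked transcription factor gene, had a log2 ratio of 0.49. Among 19 measured markers of hormone-sensing luminal cells, 1 was higher and 3 lower, with a median of -0.09 at percentile 0.415. The stem cell surface gene Ly6a was at 138.17 and 220.18 FPKM, while Prom1, a membrane glycoprotein gene, was at 48.96 and 28.63 and the orphan receptor gene Esrrb at 2.05 and 1.03. Receptor cofactors and related nuclear receptors, 22 measured, had 1 lower member (Esrrb) and a median of -0.15, at percentile 0.660 on expression but 22.9 with length matched. The coactivator genes Ncoa2 and Ep300 had log2 ratios of -0.44 and -0.41.

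Genes of milk production lay mostly on the side of Ctrl, with 14 of 18 measured log2 ratios below 0. By 1.5-fold or more 5 were lower and 3 higher, with a median of -0.26, below all but 0.01% of the lists matched on expression and length. Btn1a1, needed for milk fat secretion, was at 18.47 and 8.33 FPKM, and Wap was among the lowest genes of all. Glycam1, a milk mucin gene, ran the other way with 1 read in Ctrl and 56 in CKO, a ratio of 58.8 with a log2 interval of 3.40 to 11.26, and the fatty acid carrier gene Fabp3 was at 0.19 and 1.91 FPKM. Markers of luminal progenitor and alveolar cells, 20 measured, had 1 higher and 3 lower members and a median of 0.00 at percentile 15.6. The neutrophil attractant gene Cxcl1 was at 79.5 and 180.21 FPKM, the iron carrier gene Trf at 715.71 and 444.01, the Notch target Hey1 at 6.94 and 3.36, and the tetraspanin gene Tspan8 at 13.46 and 7.84. Genes of Notch, Wnt and paracrine signals, 19 measured, had 1 lower member, Hey1, and a median of -0.09 at percentile 14.9. The log2 ratio of the ligand gene Wnt5a was -0.53 and of the receptor gene Erbb3 -0.47.

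Genes of G2 and mitosis were higher in the CKO library. Of 30 listed G2/M genes, 11 reached the mean of 1 FPKM, and of these 6 were higher and 0 lower, with a median of 0.71 above all random lists (percentile 100). Of those 6, 4 were under 1 FPKM in Ctrl and entered through their CKO value. Over all 30 genes with no minimum, a count added after the result was seen, 12 were higher and 0 lower, 29 log2 ratios were above 0, and the summed reads of 903 and 1438 gave a log2 ratio of 0.80 (0.68 to 0.92). The 7 genes at 1 FPKM or more in Ctrl had 2 higher members and a median of 0.39. These genes were weakly expressed: the mitotic cyclin gene Ccnb2 was at 0.52 and 1.95 FPKM, the survival and spindle gene Birc5 at 0.66 and 2.01, the mitotic kinase gene Plk1 at 0.62 and 1.58, and the ubiquitin-conjugating gene Ube2c at 3.19 and 6.25. Of 22 measured G1/S genes, Ccnd1 alone was counted as higher and 0 as lower, and the median was 0.09 at percentile 99.1. The replication gene Gins2 had a log2 ratio of 0.50, the helicase gene Mcm6 0.23 and the licensing gene Cdt1 0.34. The network of D cyclins, their kinases and the retinoblastoma family, 18 measured, had 1 higher member, Ccnd1, and a median of 0.13 at percentile 99.5. The kinase genes Cdk6 and Cdk4 had log2 ratios of 0.36 and 0.21, and Rb1 -0.30.

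Markers of basal myoepithelial cells were higher in the CKO library. Of 18 measured, 10 were higher and 1 lower, with a median of 0.64 above all random lists (percentile 100). The basal keratin gene Krt14 was at 44.49 and 90.79 FPKM, smooth muscle actin (Acta2) at 33.68 and 66.72, and smooth muscle myosin (Myh11) at 4.91 and 9.71. The basal regulator gene Trp63 ran the other way, at 2.96 and 1.05 FPKM. The most abundant member, the growth factor binding gene Igfbp5, chosen after its values were seen, was at 235.1 and 166.12 FPKM, and with it the summed reads of the list gave a log2 ratio of -0.09.

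Epithelial junction and identity genes, 30 measured, had 1 higher member (Krt18) and 1 lower, and a median of -0.04 at percentile 0.610. The log2 ratio of Krt18 was 0.65, against 0.21 for Krt8. The desmosome gene Dsp was at -0.42, and the epithelial transcription factor genes Grhl3 and Ehf at -0.65 and -0.37. Mesenchymal genes, 14 measured, had 1 higher and 2 lower members and a median of 0.02 at percentile 78.8. The matrix gene Sparc had a log2 ratio of 0.58, the matrix protease gene Mmp2 0.59, the intermediate filament gene Vim 0.48 and the receptor kinase gene Axl -0.59.

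Markers of other cells that a sort could carry gave mixed values. Of 10 measured myeloid markers, 4 were higher and 0 lower. The list median was 0.59 at percentile 100 (-0.02 to 0.79, bootstrap over genes). The class II antigen presentation genes Cd74, H2-Ab1 and H2-Aa had log2 ratios of 0.93, 0.77 and 0.66, and the neutrophil gene S100a8 0.91. The other members, named after their values were seen, went both ways. Lyz2 and C1qa had log2 ratios of 0.52 and 0.66, Cd68 and Csf1r 0.22 each, and C1qb and C1qc -0.25 and -0.75. Among these, only the interval of Lyz2 (0.09 to 1.10) excluded a ratio of 1. Fibroblast markers, 6 measured, had 0 higher and 0 lower and a median of -0.08 at percentile 49.0, with the collagen gene Col1a2 at -0.35 and the proteoglycan gene Dcn at 0.26. Endothelial and pericyte markers, 13 measured, had 1 lower, Flt1, and a median of 0.05 at percentile 92.4. Their vessel genes Pecam1, Vwf and Eng had log2 ratios of 0.41, -0.22 and 0.25. Lymphocyte markers had 1 measured member, the lymphotoxin gene Ltb, at 0.65 and 1.98 FPKM. Of 3 adipocyte markers 1 was lower and the median was 0.40. The lipid regulator gene Pparg was at 1.43 and 0.59 FPKM, the lipase gene Lipe at 24.33 and 34.59, and the fatty acid binding gene Fabp4 at 33.36 and 44.19. Of 3 erythroid and muscle genes 0 passed either way and the median was -0.45, with the heme synthesis gene Alas2 at 2.31 and 1.55 FPKM and the globin gene Hba-a1 at 4.59 and 6.95.

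**Figure D2:**
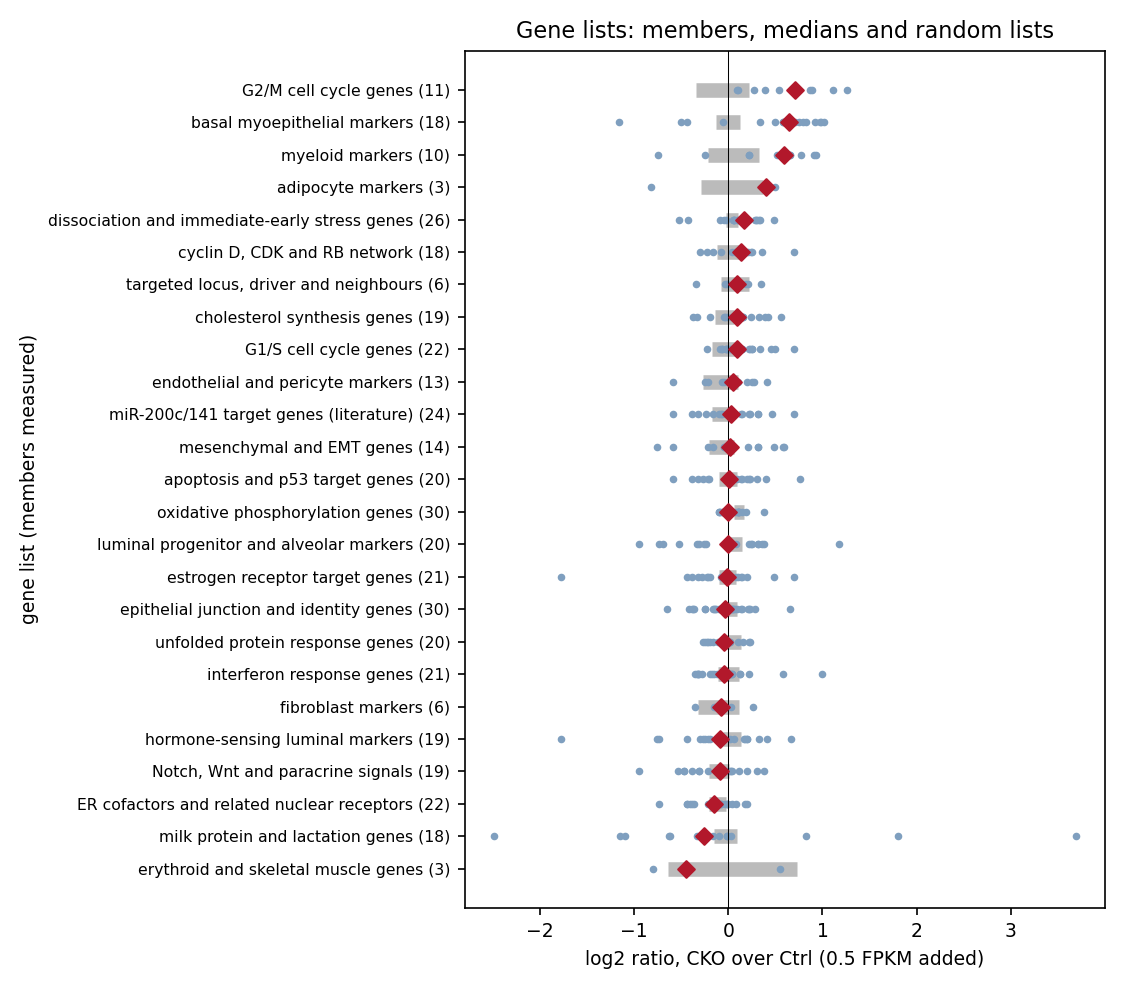
For each gene list with at least 3 measured members, blue points are the members, the red diamond is their median and the grey bar spans 95% of random lists matched on expression and length, all as log2 ratios of CKO over Ctrl. Several medians lie outside their bars, among them those of the G2/M genes (0.71), basal markers (0.64) and myeloid markers (0.59) on the right and of the milk genes (-0.26) on the left. The 7 G2/M genes at 1 FPKM or more in Ctrl had a median of 0.39.

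Stress and metabolic lists moved by small amounts. The 26 immediate-early and dissociation stress genes had 0 members past 1.5-fold and a median of 0.17 at percentile 99.9. The heat shock genes Hspa1b and Hspa1a had log2 ratios of -0.52 and -0.43, and the Hippo pathway targets Ctgf and Cyr61 0.49 and 0.34. Of 21 measured interferon response genes, 1 was higher, the immunoproteasome gene Psmb9 at 20.16 and 40.63 FPKM, and the median was -0.05 at percentile 38.4. A sister subunit gene, Psmb8, was at 59.49 and 89.16 FPKM, while the RNA sensor gene Ddx58 and the signalling gene Stat2 had log2 ratios of -0.35 and -0.32. Oxidative phosphorylation genes, 30 measured, had 0 past 1.5-fold and a median of -0.00, at percentile 4.07 on expression and 0.01 with length. The respiratory chain genes Uqcrb, Cox4i1 and Cox6c had log2 ratios of 0.38, 0.15 and 0.19, and the ATP synthase gene Atp5b -0.05. The 20 unfolded protein response genes had 0 past 1.5-fold and a median of -0.05 at percentile 3.66, with the chaperone genes Hspa5, Hyou1 and Calr at -0.19, -0.22 and -0.16 and the quality control gene Sel1l at -0.27. Cholesterol synthesis genes, 19 measured, had 0 past 1.5-fold and a median of 0.09 at percentile 97.4, with the enzyme genes Sc5d, Hmgcs1, Cyp51 and Lss at 0.56, 0.39, 0.42 and -0.38. Of 20 apoptosis and p53 target genes, the survival gene Bcl2 was higher, at 1.46 and 2.81 FPKM, and the cyclin gene Ccng1 lower, at 15.81 and 10.31. Their median was 0.01 at percentile 62.4, with the DNA damage gene Gadd45a at -0.39 and the death receptor gene Tnfrsf10b at 0.40.

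The deletion itself could not be read from the table, since the microRNA genes are not analysed here. Around the targeted locus and the Cre driver, 6 genes were measured, with 0 past 1.5-fold and a median of 0.09 at percentile 76.7. Krt8, whose promoter drives the Cre (chromosome 15, 101996698 to 102004482), was 1.16-fold higher. The neighbours of the cluster Emg1, Phb2 and Ptpn6, genes of ribosome assembly, mitochondrial scaffolding and phosphatase signalling, had log2 ratios of 0.35, 0.19 and -0.34. Of the sex-linked genes 2 are in the table and 0 reached 1 FPKM, and of the mitochondrially encoded genes 0 are in the table.

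Ratios followed transcript length across all 11667 measured genes. In the tenth of genes with the shortest transcripts (median 854 bases) the median log2 ratio was 0.11, and in that with the longest (median 7334 bases) it was -0.20. The median over all measured genes was -0.03.

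**Figure D3:**
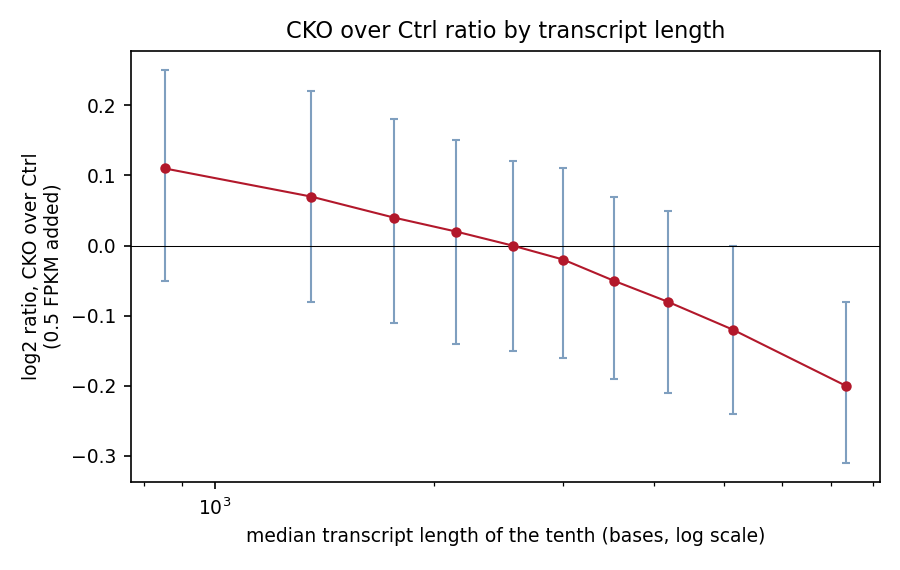
Median log2 ratio of CKO over Ctrl for the measured genes in 10 equal groups by transcript length (bases, log scale), with bars from the lower to the upper quartile. The medians pass from 0.11 in the shortest to -0.20 in the longest.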

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

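The alternatives that used the trimmed mean of M-values, no division by length, removal of the length trend, read ratios implied by the deposited p-values, or a subset of genes were chosen after seeing the data. Of 98 alternative values, 85 stayed near the value reported, 13 moved and 0 reversed. A reversal could be recorded only where the interval of the result excluded 0, so not for the gene counts or the list medians. Some alternatives could not move a value: the table is already scaled to total reads, and filters do not enter the Ccnd1 or Esr1 ratio. The log2 ratio of Ccnd1 lay between 0.64 and 0.77 over 12 alternatives, and has no value with a filter of 20 FPKM. The Esr1 ratio lay between 0.03 and 0.27. The value of 0.03 is implied by the deposited p-value on the side of the FPKM ratio, so its sign was fixed. The medians of the estrogen receptor targets (-0.08 to 0.02) and microRNA targets (0.00 to 0.11) stayed within their bootstrap intervals in all 14 alternatives each. The counts of genes at least 2-fold higher and lower (58 and 31) followed the filter, which sets how many weakly expressed genes enter. They were 110 and 91 at 1 FPKM, 139 and 125 with no filter, and 28 and 11 at 20 FPKM. Protein-coding genes alone gave 34 higher, and values not divided by length gave 69 lower. The difference between genes with and without a seed match was -0.05 with no filter, -0.05 at 20 FPKM and -0.01 with the length trend removed. The median of genes with a match lay at percentile 0 when random lists were matched on mean expression only, since UTR length then differed. The cause of the Esr1 and length effects was not tested. Other scalings moved all ratios by at most 0.03 on the log2 scale. No paired analysis was possible because the labels pair no samples, and no library could be left out with 1 per group. At this depth 3 reads amount to 0.240 FPKM in Ctrl and 0.262 in CKO for a transcript of 1 kilobase, which limits genes such as Zeb1 and Zeb2.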

Other observations

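All tests here were chosen after the result was seen, except those on the neighbours of the histocompatibility and Ifi200 genes, and so were the genes named below that neither the report nor the naming rule includes. Biological process terms in the deposited annotation were surveyed over 884 terms of 15 to 300 measured genes, each set against 10000 random lists matched on expression and length. Above the central 95% of their random lists were 42 terms and below it were 33, where 22.1 on each side would arise by chance, so most single terms carry little weight. Hedgehog (smoothened) signalling lay lowest, with 38 genes at a median log2 ratio of -0.24, below all its random lists (percentile 0). Its receptor gene Ptch1 was at 3.85 and 2.72 FPKM in Ctrl and CKO, and the cilium gene Arl3 at 16.53 and 10.44. Transport along cilia, the organelles on which this pathway depends, had 18 genes at a median of -0.19 (percentile 0.130), among them Ift57 at 7.47 and 5.74 FPKM.

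Immune terms stood at both ends. The cellular response to interferon gamma had 29 genes at a median of 0.22 (percentile 100 after rounding), and without 3 members, the class I genes H2-Q7 and H2-Q9 and the pseudogene Gapdh-ps15, a median of 0.11 (percentile 96.2). Chemokine signalling had 21 genes at 0.26 (percentile 99.8), while the negative regulation of T cell proliferation had 20 genes at -0.20 (percentile 0.0600) and the antibacterial humoral response 19 genes at -0.17 (percentile 0.1). The chemokine genes Ccl21a, at 0.68 and 5.92 FPKM, and Cxcl2, at 6.06 and 16.01, were higher in the CKO library. Krt4, a keratin of stratified epithelia, was at 2.62 and 7.18 FPKM, and the antimicrobial peptide gene Defb1, a member of the antibacterial term that ran against its median, at 3.26 and 22.78. Of 12 measured loci described as retroviral envelope, polymerase or related proteins, 9 were higher by at least 1.5-fold and 1 lower, and their estimated reads summed to 10568 in Ctrl and 23812 in CKO. LOC108169043 was at 29.39 and 122.14 FPKM and LOC108168376 at 11.74 and 36.55, while Gm6958 was at 2.58 and 1.14.

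Class I histocompatibility genes were higher in the CKO library, with 11 of 18 measured members at least 1.5-fold higher and 1 lower. Reads moving between near-identical members are argued against as the whole cause, since the summed reads of the family gave a log2 ratio of 0.58 (0.56 to 0.60). More immune cells in the CKO sort, which a luminal gate is meant to remove, stay open as an explanation. The intervals of 4 of the 18 members, Gm10499, H2-Bl, H2-Q10 and H2-T10, lay above those of all 10 measured myeloid markers. This cannot decide the question, since these members were picked by that outcome, after a first bound of 1 in 4 members was not met. Of the 4, 3 were under 1 FPKM in Ctrl, and Gm10499, H2-Bl and H2-T10 are annotated as pseudogenes in GENCODE. The only measured lymphocyte marker, Ltb, had an interval of 0.45 to 2.89, which overlapped that of H2-T10 (2.40 to 3.13). The other 14 members had a median of 0.50 (-0.28 to 1.16, bootstrap over genes). H2-D1 was at 774.38 and 1358.98 FPKM, against 17.98 and 34.79 for Cd74 and 4.42 and 6.57 for Lyz2. An interferon gamma response remains a candidate explanation: 25 other genes it induces had a median of 0.17 (0.04 to 0.34, bootstrap over genes). However, H2-T22, H2-T24 and H2-Q8 were lower, at log2 ratios of -0.51, -1.05 and -0.31. A difference in genetic background on chromosome 17 stays open too, because 136 neighbouring genes differed more than 89.9% of equal runs of genes elsewhere, short of the 95% set in advance, and the knockout itself was not tested apart from it.

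Genes of the Ifi200 family were lower in the CKO library, by at least 1.5-fold in 6 of 7 measured members. Shared reads are argued against, since the summed reads gave a log2 ratio of -4.54 (-4.78 to -4.32). A general loss of the interferon response is argued against as well, since that list had a median of -0.05 (-0.19 to 0.04, bootstrap over genes). Expression of Ifi202b is known to vary between mouse strains, so a different background at this locus may contribute, although the labels give C57BL/6. The 16 neighbours of the family between 173519717 and 174031810 of chromosome 1 and up to 2 Mb beyond lay at percentile 65.0 of equal runs. This does not settle it, and an effect of the knockout was not tested. Loci on other chromosomes, such as Gm7429 (X), Gm5601 (7), Tdg-ps (15) and Gapdh-ps15 (Y), also had reads in 1 library only. No listed sex-linked gene reached a mean of 1 FPKM. A background difference beyond the histocompatibility and Ifi200 loci was not tested.

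Basal markers had a median of 0.64 in the CKO library. Of 10 measured myeloid markers 4 were higher and 0 lower, with a median of 0.59 (-0.02 to 0.79, bootstrap over genes). Of 6 fibroblast and 13 endothelial markers, by contrast, 0 were higher. A lower share of luminal cells as the whole cause would raise all of these alike. Yet the basal median exceeded that of 19 fibroblast and endothelial markers by 0.61 (0.40 to 0.84, bootstrap over genes). More basal cells passing the luminal gate, which is meant to remove them, and basal genes switched on within luminal cells after the knockout cannot be told apart: 14 of 18 measured markers had intervals above a ratio of 1, with Krt14 at 44.49 and 90.79 FPKM, but this count restates the pattern. Trp63, Dkk3 and the most abundant member Igfbp5 were lower, and all 18 were at 1 FPKM or more in Ctrl and 2 of the list also stand in another list.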
